A study of Zea mays with 22 samples.

How the data were processed

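Kernels of the maize inbred B73, grown in a greenhouse and self-pollinated, were sampled 8 DAP (days after pollination), and 10 compartments were collected by laser-capture microdissection. Per the labels, RNA was isolated with a PicoPure kit, and 10 ng of it was amplified with oligo(dT) and random primers (Ovation RNA-Seq System V2). TruSeq libraries were sequenced on an Illumina HiSeq instrument. There are 22 libraries: 3 from each of AL, BETL, CSE, CZ, EMB and ESR, and 1 from each of NU, PC, PE and PED.

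The authors deposited a gene-level FPKM table per library, and 6 further FPKM tables in which the 3 libraries of a compartment are merged. The submitters' notes name Trimmomatic, TopHat2 2.0.9, bedtools 2.17.0, Cufflinks 2.1.1 and the genome build B73 RefGen_v3; they do not give the roles of these tools, the annotation, the filters or the options. Each table holds 109730 identifiers. No fragment counts are given, so absolute depth is unknown. Values whose upper bound is 5 times the value were read as a single fragment, and their ratios gave the depth relative to AL replicate 1. The bounds were not used as counting intervals, since only 90.5% of values above 0 lay inside their own bounds. The FPKM sums ranged from 531430 to 2121084 per library. Of all values 77% are exactly 0. Not all of these can be taken as absence, since of 1281 genes with a median above 50 FPKM, 41 are 0 in some library. Such values are given here as listed at 0, library by library, with no fold change against a group wholly at 0. The merged tables were left out of the tests; their values lay within 1.25-fold of the replicate mean for 89.7% to 97.5% of genes.

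Gene names came from a table of RefSeq genes for the assembly Zm-B73-REFERENCE-NAM-5.0, which holds 18925 of the identifiers and an informative name for 2596. It gives no positions, so none are reported. Some names belong to more than 1 identifier (pbf1, Actin-7, the histone H4C13), and 14 identifiers carry names from 2 records. Genes without such a name were tested and counted but not named.

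Genes with at least 1 FPKM in at least 3 of the 18 replicated libraries were tested (26648 genes). Values were used as log2(FPKM + 1). Linear models with a mean per compartment were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes. Each of the 6 filial compartments was compared with the mean of the other 5, and AL with CSE, BETL with CZ and BETL with AL. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. Maternal compartments, with 1 library each, were not tested. For them, genes at 10 FPKM or more and at least 1 log2 unit (pseudocount 1) above every other compartment mean were counted. Specificity was measured by tau on log2(FPKM + 1) of the 10 compartment means, for genes with a maximum of at least 1 FPKM. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

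Of 25 gene lists, 7 were fixed with their members before the data were examined, and a few members and spellings found in the name table (bap-1a, bap-3b, iso2, knox6, wox9C, Agpsemzm, AGPLS3 and GBSSIIa) were added. Members of 18 lists were taken by name from that table. In 24 lists enough members passed the filter, and these were tested with camera, with its preset correlation of 0.01 and also with an estimated correlation. The remaining list, of photosystem genes, had 2 tested members. MRP-1, a transfer cell regulator, was not found among the names. In maternal compartments the median log2 difference of a list was placed among 10000 random lists matched in size and expression.

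Comparisons, thresholds, the rule for naming genes and all alternatives not marked as later were chosen before the data were examined. The rule names, among called genes with a name and with all 3 libraries beyond all 15 others, the 10 largest rises and 4 largest falls per compartment, 6 genes each way per pair of compartments (libraries not overlapping) and 6 genes per maternal compartment. It also names, whatever their test result, up to 12 members of the lists set for a compartment. The analysis was tested on simulated data made by changing 200 of 26648 genes in AL. Against the other 5 compartments, 50% of rises of 1.5 (log2) and 96% of rises of 3 were found, and 42% and 54% of falls, with 8 false calls. Against CSE the shares were 32%, 70%, 28% and 50%, with 5 false calls. Apart from the changed genes, the simulated compartments had equal means. Noise was normal and drawn independently for each gene and library. The simulation held no correlation between genes or libraries, so its false calls give no error rate for the real data. Alternatives were the pseudocount, the filter, median-of-ratios scaling, quantile normalization, library weights, simpler empirical Bayes, leaving out each library, leaving out the embryo, a test against each other compartment separately, a replicate block, and limits for specificity and maternal counts.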

Results

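Gene expression was measured by RNA sequencing in 10 compartments of the maize kernel (inbred B73), each isolated by laser microdissection 8 days after pollination (DAP). Of the 22 libraries, 18 came from 6 filial compartments with 3 libraries each: the aleurone (AL), the basal endosperm transfer layer (BETL), the central starchy endosperm (CSE), the conducting zone (CZ), the embryo (EMB) and the embryo-surrounding region (ESR). The nucellus (NU), placenta-chalazal region (PC), pericarp (PE) and vascular region of the pedicel (PED), all maternal, had 1 library each. Expression is given in FPKM (fragments scaled by gene length and library total) as deposited, as mean ± SD with n = 3, and log2 fold changes are given ± SE. FPKM summed to between 531430 (AL replicate 1) and 2121084 (ESR replicate 3). The tables hold FPKM with interval bounds and no fragment counts, so absolute sequencing depth is unknown. Depth relative to AL replicate 1, estimated from values whose bounds mark a single fragment, ran from 1 to 4.23 (ESR replicate 1; quartiles 3.61 to 4.66).

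The compartments separated clearly. Each of the 18 replicated libraries correlated best with a library of its own compartment, with Pearson's r across genes of 0.871 to 0.925 within compartments and 0.482 to 0.886 between them; genes are not independent replicates. CSE and CZ were the closest pair of compartments (mean r = 0.863), and BETL and EMB the farthest apart (mean r = 0.507). The first principal component held 24.6% of the variance and the second 17.3%. The labels do not tie libraries to single kernels or plants, so the p-values measure the spread between these libraries, and whether some share kernels is not recorded. FPKM is relative to each library's total, so a few very abundant genes can press down the values of all others. Counts are therefore given with the deposited values and, where the share of rises moved by more than 10 percentage points, after median-of-ratios scaling. In the comparisons, the next highest compartment is the next among the 6 filial compartments. Rises and falls were ranked only among called genes that have a name.

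**Figure D1:**
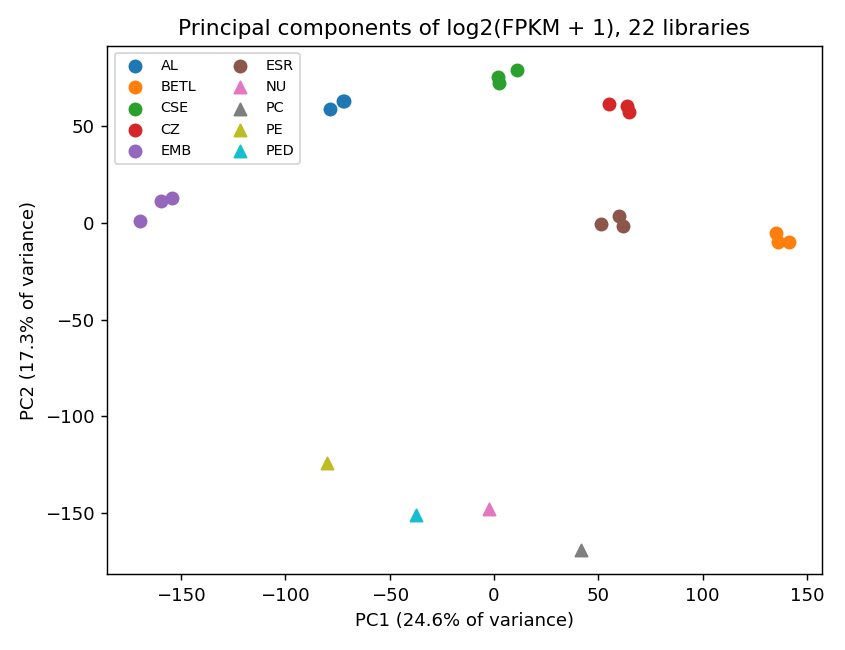
Principal components 1 and 2 of log2(FPKM + 1) over the 22 libraries, with the share of variance on each axis; circles are the 6 compartments with 3 libraries each and triangles the 4 with 1 library. The 3 libraries of each replicated compartment lie together.

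**Figure D2:**
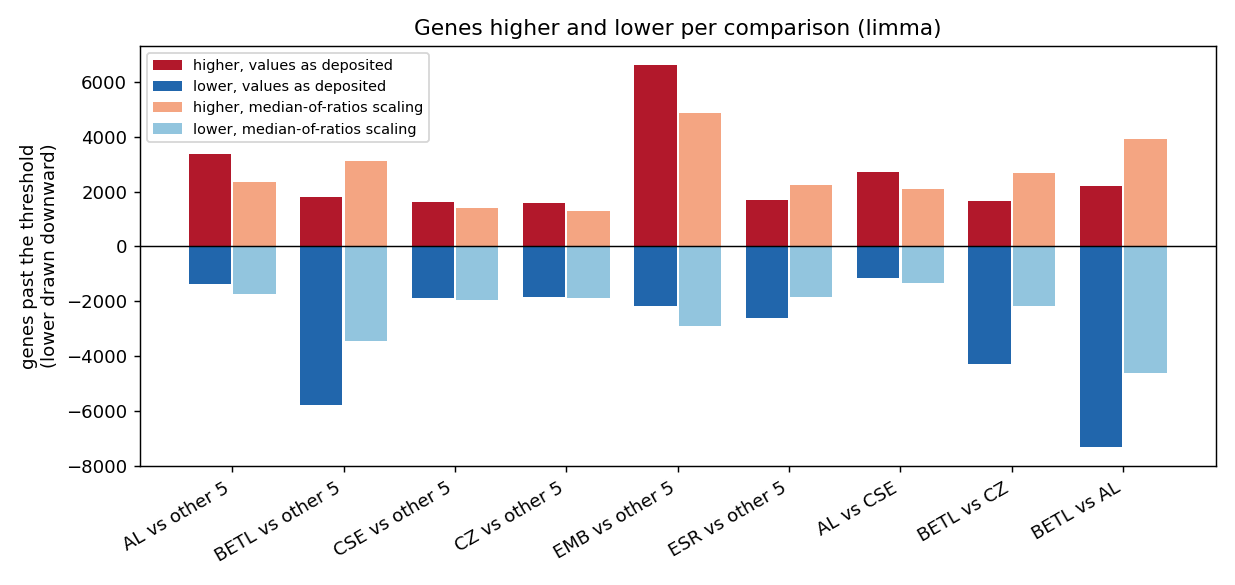
Number of genes higher (upward) and lower (downward) in each of the 9 comparisons, with the deposited values (dark bars) and after median-of-ratios scaling (light bars). In BETL against the other 5 compartments, 1815 genes were higher and 5792 lower with the deposited values, and 3128 and 3442 after scaling.

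What sets each filial compartment apart was asked by comparing it with the mean of the other 5. In the aleurone, the outer cell layer of the endosperm, vpp1 (GRMZM2G069095), a vacuolar proton pump, reached 201 ± 22.3 FPKM against 7.36 ± 1.53 in CSE, the next highest (log2 fold change 5.45 ± 0.26). The auxin synthesis gene yuc (GRMZM2G091819) was at 224 ± 20.9 FPKM (next CSE, 83.4 ± 8.58), and the auxin-conjugating enzyme gene GH3 rose by 4.92 ± 0.34 (log2). The cytokinin phosphotransfer genes ZmHP1 and ZmHP3 were at 291 ± 28.4 and 106 ± 31 FPKM, with log2 fold changes of 4.57 ± 0.38 and 4.71 ± 0.26. Pep1 (5.05 ± 0.26), per-1 (4.89 ± 0.36), ZmCASPL2D1 (4.61 ± 0.48), EREB26 (4.54 ± 0.28) and zmCL2-2 (4.03 ± 0.27) completed the 10 largest rises ranked. The ranking required all 3 AL libraries to lie above all 15 others, and limma adjusted p ran from 2.3e-09 to 1.6e-05. The 4 largest falls ranked in the same way were baf1, dhar2, the prolyl hydroxylase gene P4H6 (log2 -3.99 ± 0.20) and the alcohol dehydrogenase gene adh2 (-3.39 ± 0.27). baf1 was listed at 0 in all 3 AL libraries and at 281 ± 97.4 FPKM in BETL. For dhar2 the AL libraries were at 0, 0.52 and 1.1 FPKM and BETL at 587 ± 144.

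Of the 11 tested aleurone and epidermal genes, 6 rose in AL and 1 fell (camera adjusted p = 0.00152, and adjusted p = 0.065 with an estimated correlation). Nkd1 and Nkd2, factors of aleurone differentiation, rose by 2.20 ± 0.20 and 2.72 ± 0.26, to 74.9 ± 4.63 and 33.6 ± 8.47 FPKM; in CSE they were at 90.7 ± 28.7 and 54.5 ± 8.02. The homeodomain genes ocl1 and ocl4 rose by 2.73 ± 0.36 and 2.81 ± 0.22, ocl5 was at 16.1 ± 4.55 FPKM (EMB 16.7 ± 3.39), and ocl3 fell by 1.72 (below the fold threshold with a pseudocount of 5). The receptor kinase gene cr4 (0.88 ± 0.18, limma adjusted p = 0.00143) stayed under the fold threshold, and dek1 (-0.22 ± 0.25), Sal1 (-0.24 ± 0.28) and plt1 (1.00 ± 0.73) did not pass the test. This list was not particular to AL. In EMB 7 of its members rose and 0 fell (camera adjusted p = 0.0446, and adjusted p = 0.195 with an estimated correlation). The EMB call was lost with a pseudocount of 5 (camera adjusted p = 0.0788) and the filter at a mean of at least 5 FPKM (0.128). All 8 core histone genes rose in AL, 5 after median-of-ratios scaling, for example his2b5 at 279 ± 166 FPKM (camera adjusted p = 8.2e-05, and adjusted p = 0.219 with an estimated correlation). Among 27 DNA replication and cell division genes, 11 rose (7 after scaling) and 1 fell (camera adjusted p = 9.1e-05, and adjusted p = 0.00984 with an estimated correlation); cyc3 was at 58.3 ± 7.65 FPKM in AL and 4.74 ± 0.861 in CSE. Of 20 auxin genes, 10 rose and 1 fell (camera adjusted p = 0.00439, and adjusted p = 0.109 with an estimated correlation; lost with no filter, adjusted p = 0.0539). Of 9 oil body, globulin and dehydrin genes, 6 rose and 1 fell (camera adjusted p = 0.0183, and adjusted p = 0.0954 with an estimated correlation; lost with the filter at a mean of at least 5 FPKM, adjusted p = 0.156), with ole1 at 627 ± 333 FPKM. Of the 5 embryo-surrounding region markers 5 fell (camera adjusted p = 5.6e-04, and adjusted p = 0.117 with an estimated correlation), as did 3 (4 adjusted over the list alone) of 10 cystatin and protease inhibitor genes (camera adjusted p = 0.0296, and adjusted p = 0.205 with an estimated correlation).

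In all, limma called 3367 genes higher and 1371 lower in AL, of 26648 tested; after scaling these were 2353 and 1735. The median log2 fold change over all genes was 0.14 with the deposited values and -0.04 after scaling.

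The basal endosperm transfer layer, which takes up nutrients from maternal tissue, was marked by its known marker genes. The cell wall invertase gene mn1 (GRMZM2G119689) was at 11741 ± 3064 FPKM, against 19.7 ± 14.3 in ESR (ESR being the next highest), a log2 fold change of 11.13 ± 0.60. The small secreted protein genes betl10 (GRMZM2G091445), betl-9 and betl2 reached 31304 ± 4665, 29071 ± 7993 and 17560.3 ± 3825 FPKM. The imprinted gene MEG1 was at 15388 ± 5046 FPKM and the response regulator gene tcrr-1 at 1190.0 ± 251. Only 126 of the 1815 called rises were of genes with a name. Among these, the 10 largest rises ranked were all transfer cell markers. Their log2 fold changes ran from 8.39 ± 0.47 (bap-3b) to that of mn1, and limma adjusted p from 2.6e-10 to 1.3e-06. They included betl3 (9.65 ± 0.60), betl4 (8.93 ± 0.57), bap-3a (9.36 ± 0.45), bap1-b (8.65 ± 0.50) and bap-1a (8.55 ± 0.50). The ranking required all 3 BETL libraries to lie above all 15 others for each. Among the less abundant markers were BETL1 (477 ± 103 FPKM, log2 6.40 ± 0.33) and ebe2 (54.6 ± 6.63 FPKM, log2 4.60 ± 0.15). Falls were likewise ranked only among named genes, with all 3 BETL libraries below all 15 others. The 4 largest of these were Nkd1 (-3.81 ± 0.20), the glucanase gene exg1 (-3.43 ± 0.18), the small heat shock gene hsp18f (-3.34 ± 0.36) and Actin-7 (-3.29 ± 0.18).

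Of the 14 tested transfer cell markers, 14 rose in BETL (camera adjusted p = 1.9e-23, and adjusted p = 0.0246 with an estimated correlation). Members of the betl, bap and esr families resemble each other in sequence, so how reads were shared among them is uncertain. Of 10 cystatin and protease inhibitor genes, 3 rose (5 after scaling) and 0 fell (camera adjusted p = 0.00309, and adjusted p = 0.117 with an estimated correlation), with cc8 at 5407 ± 1361 FPKM in BETL and 1323 ± 203 in ESR. The sucrose transporter gene sut1 was at 141 ± 26.1 FPKM in BETL. Several groups fell beyond the median of all genes (-0.45). Of 24 starch synthesis genes, 17 fell, 15 after scaling (median -1.79, camera adjusted p = 9.3e-06, and adjusted p = 0.0275 with an estimated correlation). Of 27 DNA replication and cell division genes, 18 fell, 15 after scaling (median -1.43, camera adjusted p = 2.0e-05, and adjusted p = 0.00672 with an estimated correlation). The 8 core histone genes all fell, 6 after scaling (median -1.84, camera adjusted p = 0.00309, and adjusted p = 0.38 with an estimated correlation). Of 34 ribosomal protein genes, 27 fell (median -1.22), but only 7 after scaling (camera adjusted p = 4.0e-09, and adjusted p = 0.188 with an estimated correlation). Of 11 heat shock genes 7 fell (camera adjusted p = 0.0172, and adjusted p = 0.206 with an estimated correlation).

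With the deposited values, limma called 1815 genes higher and 5792 lower in BETL; after scaling these were 3128 and 3442. The median log2 fold change of all genes moved from -0.45 to -0.13, so the excess of falls was smaller after scaling, while the named genes and gene groups above kept their direction on both scales. With the threshold against each other compartment the balance turned over (741 higher and 574 lower).

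The central starchy endosperm, the storage tissue, was marked by starch and storage protein genes. The gamma zein gene zp27 (GRMZM2G138727) was at 3146 ± 557 FPKM against 139 ± 52.6 in CZ (log2 7.50 ± 0.34). The sucrose synthase gene sh1 (GRMZM2G089713) was at 855 ± 326 FPKM, against 86.8 ± 8.73 in EMB and 1.52 ± 1.12 in CZ (log2 7.39 ± 0.27). The ADP-glucose pyrophosphorylase genes sh2 and bt2 rose by 6.65 ± 0.24 and 4.40 ± 0.30, and bt1, the ADP-glucose transporter of the amyloplast, by 6.06 ± 0.37. The zein activator gene o2 was at 81.9 ± 30.8 FPKM (next AL, 10.4 ± 3.92; log2 4.87 ± 0.37). The legumin gene leg1 (6.43 ± 0.36), the globulin gene glb3 (5.89 ± 0.41), the zein gene zp15 (4.52 ± 0.40) and hao1 (4.28 ± 0.21) completed the 10 largest rises ranked. The ranking required the 3 CSE libraries to lie above all 15 others, and limma adjusted p ran from 1.1e-10 to 1.3e-06. The 4 largest falls ranked in the same way were the proton pump gene mha2 (-3.06 ± 0.25), the glutamine synthetase gene gln2 (-2.63 ± 0.34), cda1 (-2.35 ± 0.34) and LAZ1-6. The last was listed at 0 in all 3 CSE libraries (BETL 9.44 ± 0.999 FPKM) and missed the fold threshold with a pseudocount of 5.

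Of 24 starch synthesis genes, 15 rose in CSE and 3 fell (camera adjusted p = 2.5e-07, and adjusted p = 0.0133 with an estimated correlation); the branching enzyme gene SBEIIb was at 451 ± 128 FPKM in CSE and 223 ± 51.5 in CZ. All 4 tested zein genes rose (camera adjusted p = 2.7e-08, and adjusted p = 0.00872 with an estimated correlation), 4 being those of 31 listed genes that passed the expression filter; reads of near-identical zein genes cannot be assigned with certainty. Of 11 storage protein regulators, 5 (6 adjusted over the list alone) rose and 0 fell (camera adjusted p = 0.00154, and adjusted p = 0.0275 with an estimated correlation). Besides o2 these were Opaque11 (2.24 ± 0.24), fl3 (2.99 ± 0.30), 1 of the 2 identifiers named pbf1 (log2 3.22 ± 0.21) and GBF1 (1.56 ± 0.41, limma adjusted p = 0.0116). The GBF1 call was lost without CSE replicate 1 (adjusted p = 0.0742) or replicate 3 (adjusted p = 0.0519). The other pbf1 identifier (log2 -0.25 ± 0.18), O10 (-0.11 ± 0.28), Floury1 (1.09 ± 0.43), ohp1 (-0.20 ± 0.21), ohp2 (-0.30 ± 0.29) and MADS47 (-0.33 ± 0.38) did not pass over all genes. Of 34 ribosomal protein genes 20 rose, 13 after scaling (camera adjusted p = 1.9e-19, and adjusted p = 0.065 with an estimated correlation); RPL19 was at 630.0 ± 91.5 FPKM in CSE and 130.2 ± 23.1 in BETL. Of 11 heat shock genes 4 rose (camera adjusted p = 3.8e-05, and adjusted p = 0.065 with an estimated correlation). All 14 transfer cell markers and all 5 embryo-surrounding region markers fell (camera adjusted p = 8.2e-12, and adjusted p = 0.0931 with an estimated correlation; for the latter list camera adjusted p = 6.4e-05, and adjusted p = 0.0861 with an estimated correlation). Of 24 embryo and meristem regulators 10 fell (camera adjusted p = 2.4e-07, and adjusted p = 0.00426 with an estimated correlation). Of 9 oil body, globulin and dehydrin genes 5 fell (3 after scaling) and 1, glb3, rose (camera adjusted p = 0.0257, and adjusted p = 0.109 with an estimated correlation; lost with a pseudocount of 0.1, adjusted p = 0.0543 and the filter at a mean of at least 5 FPKM, 0.156). In all, limma called 1628 genes higher and 1891 lower in CSE. This balance turned over with EMB left out (1874 higher and 1398 lower), a pseudocount of 5 (898 higher and 576 lower), the filter at a mean of at least 5 FPKM (1240 higher and 1178 lower), quantile normalization (1587 higher and 1522 lower), the threshold against each other compartment (65 higher and 34 lower) and without CSE replicate 1 (1487 higher and 1431 lower).

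The conducting zone lies between BETL and CSE. Rises were ranked only among named genes with the 3 CZ libraries above all 15 others. The largest of these was fl3 (GRMZM2G006585), a PLATZ protein gene, at 3776 ± 1129 FPKM against 1237 ± 253 in CSE (log2 4.89 ± 0.30). Chaperone genes were among the 10 largest rises ranked. The small heat shock gene hsp18c was at 37.5 ± 24.3 FPKM (log2 4.15 ± 0.31), the disaggregase gene hsp101 at 44.1 ± 12.4 (log2 3.76 ± 0.49) and hsp70-5 at 291 ± 37.5 (log2 3.10 ± 0.26). The cystatin gene cc10 was at 190.3 ± 71.1 FPKM (log2 4.58 ± 0.67). ERTC (4.48 ± 0.40), ARGOS8 (3.76 ± 0.45), the farnesyl pyrophosphate synthase gene fps (3.21 ± 0.12), LPE1 (2.94 ± 0.27) and the annexin gene Ann8 (2.69 ± 0.33) were the others of the 10. For the 10, limma adjusted p ran from 7.5e-10 to 1.6e-04. Of the falls ranked in the same way, that of the fructokinase gene frk2 was the largest. The CZ libraries were at 0, 0.726 and 0.484 FPKM and EMB at 823 ± 119. The phytase gene PAPhy (-3.18 ± 0.31), RIP1 (-2.54 ± 0.24) and ZmHP3 (-2.33 ± 0.26) also fell.

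Of 11 heat shock genes, 8 (9 adjusted over the list alone) rose in CZ and 0 fell (camera adjusted p = 7.1e-08, and adjusted p = 0.0246 with an estimated correlation); hsp22 was at 1132 ± 139.6 FPKM in CZ, 995 ± 467 in CSE and 23.7 ± 14.5 in BETL. Transfer cell markers rose in CZ too, 12 of 14 being called (camera adjusted p = 3.5e-07, and adjusted p = 0.184 with an estimated correlation). The marker betl-9 was at 7825 ± 2527 FPKM in CZ, and betl10 at 2036 ± 1003. These were 26.9%, the highest share among the markers, and 6.5% of their BETL levels. By contrast mn1 was at 11.7 ± 7.14 FPKM and did not pass the test (limma adjusted p = 0.293). Of 11 storage protein regulators 4 rose (camera adjusted p = 0.00221, and adjusted p = 0.0319 with an estimated correlation), and of 24 starch synthesis genes 10 rose and 3 fell (camera adjusted p = 0.0186, and adjusted p = 0.178 with an estimated correlation). Of 12 sugar transport and cleavage genes 3 (4 adjusted over the list alone) fell (camera adjusted p = 0.00439, and adjusted p = 0.0931 with an estimated correlation). Of 8 core histone genes 4 fell (camera adjusted p = 0.00122, and adjusted p = 0.32 with an estimated correlation). Of 24 embryo and meristem regulators 9 (10 adjusted over the list alone) fell and 1, wox2A, rose (camera adjusted p = 1.0e-06, and adjusted p = 0.00446 with an estimated correlation). The 5 embryo-surrounding region markers all fell (camera adjusted p = 0.00122, and adjusted p = 0.137 with an estimated correlation), as did 5 of 11 aleurone and epidermal genes (camera adjusted p = 0.0183, and adjusted p = 0.137 with an estimated correlation; lost with a pseudocount of 0.1, adjusted p = 0.115). In all, limma called 1576 genes higher and 1862 lower in CZ. This balance turned over with EMB left out (1348 higher and 1115 lower), a pseudocount of 5 (800 higher and 570 lower) and the threshold against each other compartment (67 higher and 15 lower).

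In the embryo, plt1 (GRMZM2G101958) was at 2918 ± 775 FPKM, with AL the next highest (log2 9.84 ± 0.73). The lipid transfer gene LTP3 rose by 9.21 ± 0.27 and the defensin gene DEF1 by 8.74 ± 0.31. The embryo regulator lec1 (GRMZM2G011789) was at 179.7 ± 31.6 FPKM and listed at 0 in 14 of the 15 other libraries (log2 7.35 ± 0.30). The YABBY gene yab14 was at 94.8 ± 6.04 FPKM and listed at 0 in all 15 others. The auxin efflux gene PIN1d was at 80.1 ± 14.2 FPKM (log2 6.26 ± 0.18), and the sucrose synthase gene sus1 at 1444 ± 214 (next AL, 795 ± 70.9; log2 6.30 ± 0.41). The cell wall protein gene HRGP (7.09 ± 0.36), aic1 (6.54 ± 0.24) and the wax synthesis gene CER1 (6.37 ± 0.19) completed the 10 largest rises ranked. The ranking required all to lie above all 15 other libraries, and limma adjusted p ran from 8.8e-14 to 2.5e-08. The 4 largest falls ranked in the same way were TA1 (-6.21 ± 0.36), endo1 (-6.11 ± 0.22), psk1 (-5.89 ± 0.38) and the sorbitol dehydrogenase gene sdh1 (-5.72 ± 0.43). The values of sdh1 were 16.9 ± 9.67 FPKM in EMB and 1958 ± 899 in BETL.

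Of 24 tested embryo and meristem regulators, 20 (21 adjusted over the list alone) rose in EMB and 0 fell (camera adjusted p = 1.1e-11, and adjusted p = 9.7e-04 with an estimated correlation). The homeobox genes kn1, gnarley1, lg3 and lg4b rose by 5.58 ± 0.17, 4.05 ± 0.17, 3.30 ± 0.31 and 3.03 ± 0.18, and rs1 was at 9.4 ± 1.1 FPKM and listed at 0 in all 15 other libraries. vp1 (4.66 ± 0.27) and lg4a (1.69 ± 0.32) rose as well, lg4a being as high in ESR (14.1 ± 3.29 FPKM against 13.3 ± 3.39). wox9A rose by 1.88 ± 0.24, a call lost with a pseudocount of 5. knox6 (0.83 ± 0.23) stayed under the fold threshold, and knox7 (-0.37 ± 0.25) and wox2A (-0.52 ± 0.29) did not pass. Of 27 DNA replication and cell division genes, 20 rose (15 after scaling) and 0 fell (camera adjusted p = 2.0e-05, and adjusted p = 0.00672 with an estimated correlation), such as RNRS2 at 44.3 ± 2.7 FPKM. All 8 core histone genes rose, 7 after scaling (camera adjusted p = 0.00249, and adjusted p = 0.368 with an estimated correlation). Of 16 jasmonate and wound genes 9 rose and 1 (2 adjusted over the list alone) fell (camera adjusted p = 0.0369, and adjusted p = 0.318 with an estimated correlation; lost with no filter, adjusted p = 0.0859 and the filter at a mean of at least 5 FPKM, 0.156). This call was lost without EMB replicate 1, 2 or 3 (adjusted p = 0.166, 0.306 and 0.128), BETL replicate 2 (0.0532), CZ replicate 1 (0.0509) or ESR replicate 1 (0.0503). It was also lost with replicate number as a block (camera adjusted p = 0.0505). All 14 transfer cell markers fell (camera adjusted p = 8.2e-12, and adjusted p = 0.0931 with an estimated correlation), as did all 4 zein genes (camera adjusted p = 4.8e-04, and adjusted p = 0.0627 with an estimated correlation), 4 of 11 storage protein regulators (camera adjusted p = 0.00509, and adjusted p = 0.0476 with an estimated correlation), 4 of 11 heat shock genes (camera adjusted p = 0.00726, and adjusted p = 0.184 with an estimated correlation), 5 of 10 cystatin and protease inhibitor genes (camera adjusted p = 0.0118, and adjusted p = 0.174 with an estimated correlation) and 4 of 7 Polycomb and imprinted genes (camera adjusted p = 0.00439, and adjusted p = 0.057 with an estimated correlation). Of the last, fie1 was at 0, 0 and 0.583 FPKM in EMB and 65.4 ± 9.2 in CSE, and 1 gene, fie2, rose.

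With the deposited values, limma called 6612 genes higher and 2161 lower in EMB; after scaling these were 4859 and 2885, and the median log2 fold change moved from 0.31 to 0.05.

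In the embryo-surrounding region, endosperm cells next to the embryo, the marker genes of the region reached very high values. esr2 (GRMZM2G315601) was at 55407 ± 4796 FPKM, esr1 (GRMZM2G046086) at 23760.5 ± 4534, ESR3 at 16376 ± 8017 and esr6 at 14328 ± 2203. In EMB, esr2 and esr1 were at 85.2 ± 54.4 and 21.3 ± 1.98. Their log2 fold changes were 10.63 ± 0.56, 10.71 ± 0.41, 10.68 ± 0.65 and 10.22 ± 0.55. The other 6 of the largest rises were MADS42 (5.67 ± 0.34), the phosphate transporter gene pht13 (4.64 ± 0.33), ms8 (4.57 ± 0.32), the glutathione transferase gene gst23 (4.55 ± 0.18), the aquaporin gene NIP1-1 (4.48 ± 0.31) and LOB33 (4.33 ± 0.62). The ranking required all to lie above all 15 other libraries, and limma adjusted p ran from 3.5e-11 to 8.2e-05. The 4 largest falls ranked in the same way were the starch phosphorylase gene pho1 (-3.29 ± 0.20), his2a1 (-2.55 ± 0.20), the phosphoglycerate kinase gene Pgk-2 (-2.37 ± 0.21) and bx8 (-2.18 ± 0.44).

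All 5 tested embryo-surrounding region markers rose in ESR (camera adjusted p = 1.1e-11, and adjusted p = 0.00984 with an estimated correlation), ae3 by 3.41 ± 0.21. Of 16 MADS-box genes 5 rose and 0 fell (camera adjusted p = 9.8e-04, and adjusted p = 0.046 with an estimated correlation; lost with the filter at a mean of at least 5 FPKM, adjusted p = 0.0764), for example MADS11 at 8.87 ± 2.67 FPKM. Of 14 transfer cell markers 6 (8 adjusted over the list alone) rose (camera adjusted p = 0.00118, and adjusted p = 0.384 with an estimated correlation); betl10 was at 1267 ± 676 FPKM in ESR. Of 27 DNA replication and cell division genes 10 fell and 1 rose (camera adjusted p = 1.3e-05, and adjusted p = 0.00672 with an estimated correlation), and of 8 core histone genes 6 (7 adjusted over the list alone) fell (camera adjusted p = 3.4e-04, and adjusted p = 0.266 with an estimated correlation). Of 34 ribosomal protein genes 16 fell, 10 after scaling (camera adjusted p = 8.0e-12, and adjusted p = 0.137 with an estimated correlation). Of 24 starch synthesis genes 11 fell (camera adjusted p = 3.4e-04, and adjusted p = 0.0627 with an estimated correlation), and all 4 zein genes fell (camera adjusted p = 0.00165, and adjusted p = 0.0861 with an estimated correlation). With the deposited values, limma called 1693 genes higher and 2620 lower in ESR; after scaling these were 2246 and 1832, and the median log2 fold change moved from -0.18 to -0.02. The balance also turned over with quantile normalization (2283 higher and 2220 lower) and the threshold against each other compartment (410 higher and 75 lower). The 10 most abundant genes held 53.8% to 71.8% of the FPKM sum in the ESR libraries. These sums were 1121297, 1521751 and 2121084, so they were not fixed. Whether the abundant genes lowered the other values in ESR was not tested.

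**Figure D3:**
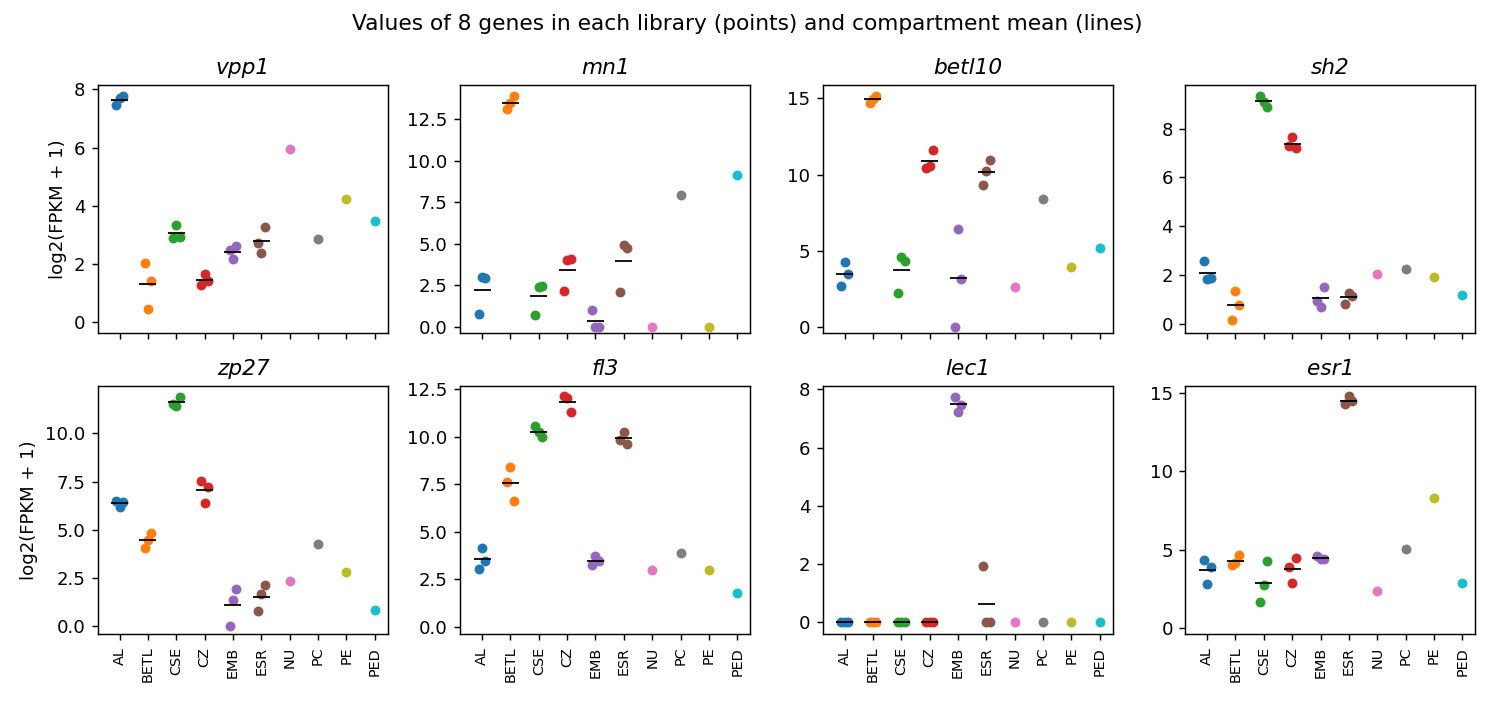
log2(FPKM + 1) of 8 genes (vertical axes) in each library, by compartment (horizontal axes); points are libraries and lines are means of the 3 libraries of a compartment. mn1 and betl10 peak in BETL, sh2 and zp27 in CSE, fl3 in CZ, lec1 in EMB, esr1 in ESR and vpp1 in AL.

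**Figure D4:**
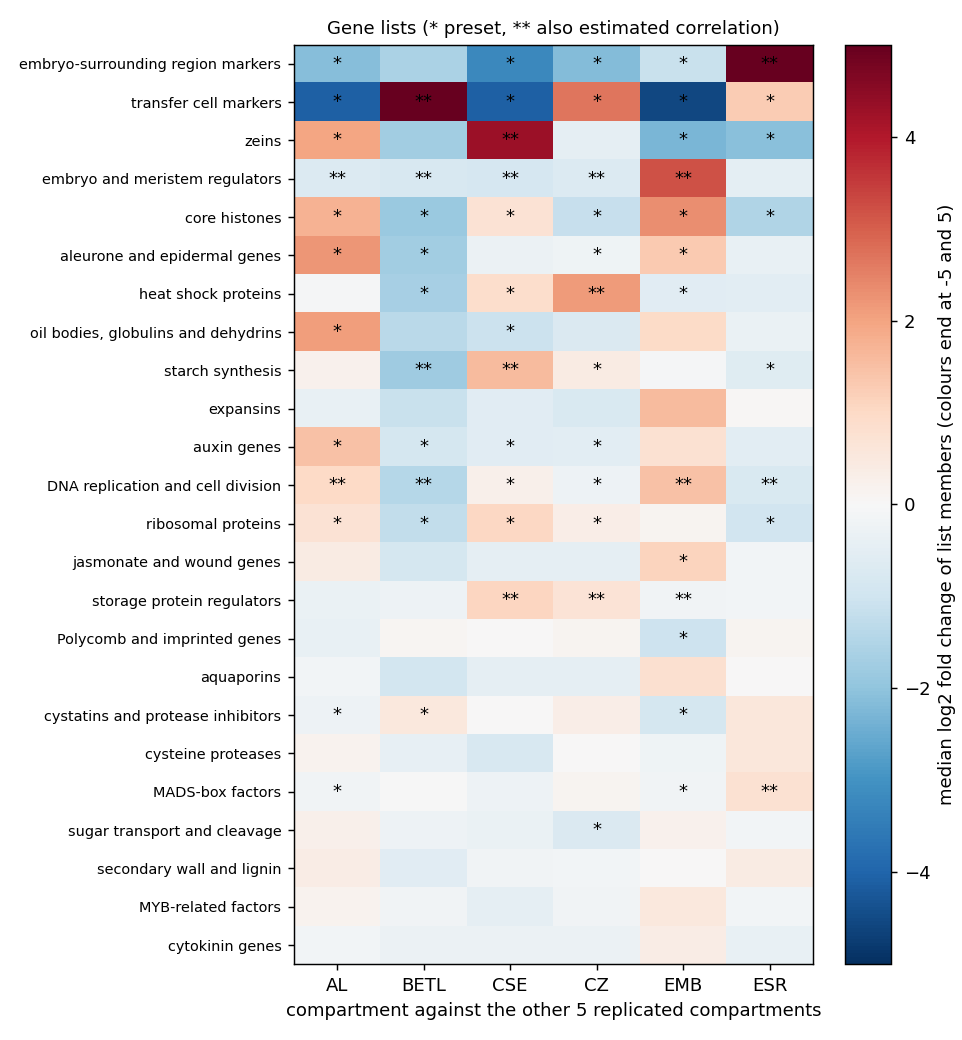
Median log2 fold change of the members of 24 gene lists (vertical axis) in each of the 6 compartments against the other 5 (horizontal axis); colours end at -5 and 5. Asterisks mark 67 of the 144 pairs of list and comparison with a camera adjusted p under 0.05, and double asterisks the 19 that kept it with an estimated correlation.

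Over the 24 lists and 6 comparisons, 67 of 144 pairs passed camera with its preset correlation, and 19 of these with a correlation estimated from the data. Counts adjusted over the list alone differed in 22 pairs, by at most 2 genes, and stand beside the counts given here. Members named as examples, other than those taken by the rule for named genes, were chosen after their values were seen.

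The outer and the inner storage endosperm were compared directly. The oleosin gene ole1 was at 627 ± 333 FPKM in AL, and the CSE libraries were at 3.12, 2.85 and 0. sus1 was at 795 ± 70.9 in AL and 2.77 ± 1.72 in CSE (log2 7.81 ± 0.52), whereas sh1, the other abundant sucrose synthase gene, was at 3.72 ± 1.34 and 855 ± 326 (log2 -7.47 ± 0.34). per-1, Pep1, ocl4 and GH3 were also among the 6 largest rises in AL; their CSE libraries were at 0, 0.355 and 0.666 FPKM for per-1, 0, 0.813 and 0.774 for Pep1, 0, 0.108 and 0.784 for ocl4 and 0, 1.55 and 2.08 for GH3. The 6 largest falls were sh1, sh2 (-7.03 ± 0.30), fl3 (-6.71 ± 0.39), glb3 (AL libraries at 0, 1.69 and 1.63 FPKM), Bk2L6 (AL libraries at 0, 0.659 and 2.43) and zp27 (-5.23 ± 0.44). The 12 genes were named only where the 3 AL and 3 CSE libraries do not overlap, which chance gives for 10% of genes; they had limma adjusted p from 6.2e-09 to 5.2e-07 for rises and 8.5e-10 to 4.6e-06 for falls. Here limma called 2695 genes higher and 1149 lower in AL than in CSE; the counts were 1775 and 1511 with quantile normalization, and the median log2 fold change was 0.15, 0.04 after median-of-ratios scaling.

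BETL was also compared with the conducting zone above it. Transfer cell markers were present in both, in CZ at 0.1% (mn1) to 26.9% (betl-9) of their BETL level. Whether a part of them came from captured BETL cells stays open. mn1 was higher in BETL by 10.05 ± 0.77 (log2), tcrr-1 by 7.77 ± 0.80, the expansin gene expB7 by 7.32 ± 0.46, bap-3a by 6.69 ± 0.58 and betl3 by 6.32 ± 0.77. The sucrose transporter gene sut1 was at 141 ± 26.1 FPKM in BETL, and the CZ libraries were at 0.512, 0.387 and 0. Lower in BETL were sh2 (-6.62 ± 0.30), bt1 (-5.88 ± 0.48), leg1 (-5.80 ± 0.47), hsp22 (-5.73 ± 0.58), Ppdk1 (-5.09 ± 0.56) and hsp18c (BETL libraries at 0.00187, 0 and 0 FPKM, CZ at 37.5 ± 24.3). For these 12 genes limma adjusted p ran from 1.8e-10 to 1.7e-05 for rises and from 4.3e-10 to 6.2e-06 for falls, the libraries being apart as the rule required. With the deposited values, limma called 1653 genes higher and 4271 lower in BETL, and 2670 and 2161 after scaling; the median log2 fold change moved from -0.28 to 0.

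Against the aleurone, the other surface layer, BETL was higher by 11.43 ± 1.12 (log2) in betl10, 11.36 ± 1.05 in betl2, 11.25 ± 0.77 in mn1, 11.16 ± 1.18 in betl-9, 11.05 ± 0.77 in betl3 and 10.86 ± 1.07 in MEG1. BETL was lower in sus1 (-8.02 ± 0.52), ole1 (-7.75 ± 0.62), yuc (-6.79 ± 0.78), leg1 (-6.55 ± 0.47), Pep1 (BETL libraries at 1.13, 0 and 0.921 FPKM, AL at 133 ± 19.9) and Ppdk1 (-6.37 ± 0.56). The rule again required libraries that do not overlap, and limma adjusted p ran from 1.7e-08 to 2.0e-06 for rises and from 1.1e-09 to 3.9e-06 for falls. limma called 2190 genes higher and 7317 lower in BETL, 3923 and 4612 after scaling; the median log2 fold change was -0.42.

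The 4 maternal compartments had 1 library each, so their differences have no replicate check and no p-value. In NU the expansin gene expB6 was at 24427 FPKM, against 146 in PE, the next highest. Cel17 (321 FPKM), TIFY1 (186), IBP1 (138), the MADS-box gene zmm16 (189) and LOB33 (780.1) followed. In PC the cytokinin oxidase gene ckx1 was at 383 FPKM (next NU, 8.2) and the beta-glucosidase gene glu1 at 1226, beside WRKY42 (89.2), id1 (160.4), gln1 (93.3) and Kiwellin-1 (26.6). In PE the expansin gene expA3 was at 102 FPKM and listed at 0 in all other libraries. DL1 (133), the aquaporin gene TIP2-1 (39.5), bHLH36 (63.6) and the lipoxygenase genes lox11 (53.6) and lox1 (166) were highest there too. In PED the glutamine synthetase gene gln3 was at 51.3 FPKM (next EMB, 0.319), beside the genes MYB59 (211), a Laccase-13 gene (60.6), a chitinase gene (22.7), pep1 (19.8) and the MADS-box gene ZAG5 (16.1). In total 857 genes in NU, 648 in PC, 879 in PE and 765 in PED were at 10 FPKM or more and at least 1 log2 unit above every other compartment. After median-of-ratios scaling, an alternative chosen after seeing the data, these counts were 1055, 1256, 563 and 615, so PC went from the fewest to the most and PE from the most to the fewest.

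Gene lists were placed among 10000 random lists of the same size and matched expression, as a description of these libraries. MADS-box genes stood at percentile 99.99 in NU, 100 in PC, 100 in PE and 100 in PED; zag2 was at 289.9, 143, 119.8 and 475 FPKM there and 1.14 ± 0.513 in BETL. In the same order (NU, PC, PE and PED), secondary wall and lignin genes stood at 15.1, 100, 96.5 and 100, with PAL1 at 284 FPKM in PC. Cytokinin genes stood at 31, 99.9, 86.6 and 100 (crr1 at 136 FPKM in PED), and auxin genes at 57.9, 69.6, 97.1 and 99.9. Expansins stood at 86.2, 61.2, 100 and 0.36, high in PE and low in PED, and jasmonate and wound genes at 6.58, 74, 99.98 and 99.8. Ribosomal protein genes stood at percentile 0 in NU, 0.65 in PC, 0.04 in PE and 0 in PED, and DNA replication genes at 0.43 in NU, 0 in PC, 0.03 in PE and 24.8 in PED.

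Compartment specificity over all 10 compartments was scored with tau, from 0 (even) to 1 (a single compartment). Of 33221 genes, those with tau of at least 0.9 peaked in EMB most often (1017), then in PED (943), PE (911), BETL (719), PC (538), NU (529), ESR (472), AL (375), CZ (296) and CSE (220). The first place depended on the limits: PE led with tau of at least 0.8 (PE 1618, EMB 1560, PED 1534), and PED with a maximum of at least 5 FPKM (PED 444, EMB 436). Named examples, chosen after their values were seen, were MYB51 at 160.2 ± 5.22 FPKM in BETL, the auxin-response gene AUX9 at 20.1 ± 15.1 in AL, zp16 at 21.1 ± 5.78 in CSE, psbs1 at 4.81 ± 0.944 in CZ, yab9 at 94.6 ± 16.1 in EMB, PYL11 at 23.4 ± 12.2 in ESR, LOB21 at 26.6 in NU, id1 in PC, bHLH30 at 34.5 in PE and FIP1 at 164 in PED. Maternal values rest on 1 library each.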

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

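The alternatives for the maternal compartments other than the FPKM limit, and those for library structure and for leaving out libraries in specificity, were chosen after seeing the data. No named gene and no list call reversed under any alternative. The balance of higher and lower genes did turn over in some counts: with median-of-ratios scaling, BETL vs CZ (2670 higher, 2161 lower) and ESR (2246 higher, 1832 lower); with the threshold against each other compartment, BETL (741 higher, 574 lower), CSE (65 higher, 34 lower), CZ (67 higher, 15 lower) and ESR (410 higher, 75 lower); with the embryo left out, CSE (1874 higher, 1398 lower) and CZ (1348 higher, 1115 lower); with a mean of at least 5 FPKM, CSE (1240 higher, 1178 lower); with pseudocount 5, CSE (898 higher, 576 lower) and CZ (800 higher, 570 lower); with quantile normalization, CSE (1587 higher, 1522 lower) and ESR (2283 higher, 2220 lower); without CSE replicate 1, CSE (1487 higher, 1431 lower). With median-of-ratios scaling, no gene was called in the opposite direction; in BETL, 1811 rises and 3440 falls were called on both scales. The following counts moved by more than 1.5 times; the cause was not tested except where the setting itself lowers the number of genes. Pseudocount 5, which shrinks fold changes at low values: AL 1539 higher and 602 lower, BETL 977 higher and 2532 lower, CSE 898 higher and 576 lower, CZ 800 higher and 570 lower, EMB 3324 higher and 1056 lower, ESR 658 higher and 1102 lower, AL vs CSE 1296 higher and 684 lower, BETL vs CZ 874 higher and 2314 lower, BETL vs AL 1283 higher and 4247 lower. Mean of at least 5 FPKM, which tests fewer genes: AL 2080 higher, BETL 933 higher, CSE 1178 lower, CZ 1119 lower, EMB 3128 higher, ESR 826 higher, AL vs CSE 1429 higher, BETL vs CZ 811 higher, BETL vs AL 1237 higher and 4839 lower. Median-of-ratios scaling: BETL 3128 higher and 3442 lower, BETL vs CZ 2670 higher and 2161 lower, BETL vs AL 3923 higher and 4612 lower. Quantile normalization: BETL 3000 higher and 3375 lower, EMB 4147 higher and 3788 lower, AL vs CSE 1775 higher, BETL vs CZ 2385 lower, BETL vs AL 3841 higher and 4606 lower. Embryo left out: CZ 1115 lower. Threshold passed against each of the other 5 compartments separately, which is stricter: AL 331 higher and 53 lower, BETL 741 higher and 574 lower, CSE 65 higher and 34 lower, CZ 67 higher and 15 lower, EMB 2057 higher and 357 lower, ESR 410 higher and 75 lower. Tau of at least 0.8, which is looser: AL 627, CSE 352, EMB 1560, NU 853, PC 924, PE 1618, PED 1534. Maximum of at least 5 FPKM for specificity: AL 98, BETL 291, CSE 65, CZ 88, EMB 436, ESR 174, NU 217, PC 267, PE 378, PED 444. Median-of-ratios scaling of maternal counts: PC 1256, PE 563.

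No count moved by more than 1.5 times in the 18 fits that each left out 1 library; the group then left with 2 libraries is assumed to vary like the others. Of 156 named gene results, 4 missed a threshold under some alternative: GBF1 in CSE, LAZ1-6 in CSE, ocl3 in AL and wox9A in EMB, all at pseudocount 5 and GBF1 also without CSE replicate 1 or 3. Of the 67 list calls, 50 were lost under some alternative: 48 of them with an estimated correlation, which left 19 calls, 16 with the filter at a mean of at least 5 FPKM, and 14 in at least 1 of the fits without a library. Methods that need fragment counts were not run. Absolute depth is unknown. Relative depth ran from 1 to 4.23, so a low value stands for fewer fragments in some libraries than in others.

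Replicate numbers were added as a block in an alternative fit, although the labels do not say that equal numbers share kernels. The block gave these counts of higher and lower genes: AL 3437 and 1419, BETL 1850 and 5878, CSE 1691 and 1962, CZ 1624 and 1931, EMB 6667 and 2212, ESR 1750 and 2706, AL vs CSE 2908 and 1247, BETL vs CZ 1697 and 4485, BETL vs AL 2239 and 7433; it called 62 lists. The 5 list calls that the block ended were MADS-box factors in AL (adjusted p = 0.0546), auxin genes in BETL (adjusted p = 0.0505), auxin genes in CSE (adjusted p = 0.0505), aleurone and epidermal genes in EMB (adjusted p = 0.0505) and jasmonate and wound genes in EMB (adjusted p = 0.0505), and it changed the call of no named gene. After compartment means were removed, libraries of equal number correlated by -0.0449 to 0.228, above 0.1 in 20 of 45 pairs, and those of different number by -0.219 to 0.0497. For 16 of the 18 libraries, the mean correlation with libraries of other compartments was highest for those of their own number. Endosperm pairs correlated by 0.133 to 0.196 for replicate 1 and 0.153 to 0.228 for replicate 3, a hint of pairing from the data. Pairs with EMB, however, reached at most 0.0362 and endosperm pairs of replicate 2 at most 0.086. Pairing was taken to need over 0.1 in all pairs, so the main fit does not pair the samples. A shared part among the endosperm libraries of replicate 1 and of replicate 3 stays open. All their pairs lay above the 0.0497 reached by libraries of different number. The main p-values leave such a part out, and the block fit takes replicate number into account.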

Other observations

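The lists and examples in this and the next paragraph were picked after their values were seen. Water channel genes were split among compartments: PIP2-4 was at 16.7 ± 5.23 FPKM in CSE and 10.8 ± 3.8 in AL, TIP3-2 at 23.3 ± 9.59 in EMB and listed at 0 in all other libraries, NIP3-1 at 198 in the PE library, and pip2b at 497 in PED and 236 in PC. SIP1-1 was at 86.9 ± 0.813 in BETL and 79.9 ± 7.61 in CZ, against 13.6 ± 3.86 in EMB. Of 15 aquaporin genes, limma called 3 higher and 2 lower in AL, 1 higher and 5 lower in BETL, 5 higher and 1 lower in CSE, 2 (3 adjusted over the list alone) higher and 4 lower in CZ, 6 higher and 5 lower in EMB, 2 higher and 3 (4 adjusted over the list alone) lower in ESR, and no camera call was made (adjusted p from 0.318 to 0.996). Some cytokinin response genes were highest in the pedicel library: RR6 was at 97.8 FPKM and crr2 at 59 in PED, with crr2 at 3.16 ± 1.86 in CSE. RR9 was at 28 ± 5.8 FPKM in EMB and 0.534 ± 0.37 in AL. Of 26 cytokinin genes, limma called 4 higher and 2 lower in AL, 2 higher and 4 lower in BETL, 1 higher and 3 lower in CSE, 0 higher and 4 lower in CZ, 7 higher and 2 lower in EMB, 1 higher and 2 lower in ESR, again with no camera call (adjusted p from 0.054 to 0.702).

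Other groups also had members moving both ways. Of 8 expansin genes, limma called 1 higher and 2 lower in AL, 1 higher and 4 lower in BETL, 0 higher and 2 lower in CSE, 1 higher and 1 (2 adjusted over the list alone) lower in CZ, 4 higher and 2 lower in EMB, 1 higher and 0 lower in ESR (camera adjusted p from 0.246 to 0.637). Of 7 cysteine protease genes, limma called 2 higher and 1 lower in AL, 0 higher and 0 lower in BETL, 0 higher and 2 lower in CSE, 1 higher and 0 lower in CZ, 1 higher and 1 lower in EMB, 1 higher and 0 lower in ESR (camera adjusted p from 0.113 to 0.946). Of 16 MYB-related genes, limma called 1 higher and 2 lower in AL, 0 higher and 2 (1 adjusted over the list alone) lower in BETL, 0 higher and 3 lower in CSE, 0 higher and 2 lower in CZ, 5 higher and 0 lower in EMB, 1 higher and 3 lower in ESR (camera adjusted p from 0.143 to 0.928). Of 12 secondary wall and lignin genes, limma called 1 higher and 1 lower in AL, 1 higher and 3 lower in BETL, 3 higher and 1 lower in CSE, 1 higher and 1 lower in CZ, 3 higher and 1 lower in EMB, 1 higher and 1 lower in ESR (camera adjusted p from 0.326 to 0.924). The lignin gene cad1 was at 74.7 ± 8.83 FPKM in EMB and 9.95 ± 3.12 in ESR. The imprinted gene NRP1 was at 199 ± 46.9 FPKM in CZ, 164 ± 33.7 in CSE and 82.1 ± 19.2 in BETL, but 0, 0.397 and 1.42 in EMB. sut1 was at 141 ± 26.1 FPKM in BETL and 50.1 in the PED library. TAR3 was at 29.8 ± 20.2 FPKM in AL, and PIN1a at 28.7 ± 7.42 in EMB.

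Of the tests in the following paragraphs, those on levels averaged over BETL and the others, on transfer cell markers, on heat shock genes and on other splits of the libraries were chosen after the result was seen, and the bounds used for them were set then. BETL had more falls than rises (5792 against 1815 genes, 23.9% of calls rising). Losses among genes of low value were tested as the cause, and the answer depended on how levels and scale were taken. Genes at 20 to 100 FPKM in the other libraries had a median log2 change of -0.71, with the upper quartile at -0.09, under the bound of 0 set beforehand. Levels taken from the other libraries favour falls in BETL, so levels averaged over BETL and the others were used as well. With these, the deposited values shifted at every level, with a median of -0.50 at 1 to 5 FPKM (707 higher, 2594 lower). At 20 to 100 FPKM the median was -0.40 (285 higher, 787 lower), and -0.36, -0.47 and -0.35 in the 3 BETL libraries. The quartiles there were -1.03 and 0.21, so the bound of 0 was not met with averaged levels. On the deposited scale, losses at low values alone would not give the excess of falls at 20 to 100 FPKM. Genes at 1 FPKM or more numbered 18024 to 18358 in BETL. Only CSE replicate 1 held fewer (17703), and all remaining libraries of the filial compartments held 18842 to 21965. Fewer genes thus reached 1 FPKM in BETL than in nearly all others. A downward shift of the deposited values lowers this count by itself, so it does not tell losses from a shift. Genes above 0 FPKM numbered 23315, 24256 and 25072 in BETL. They numbered 21539 (CSE replicate 1) to 27810 (ESR replicate 3) in the other filial libraries. Losses at low values stay open, as the scaled values go with them. After median-of-ratios scaling, with averaged levels, 1088 genes were higher and 1839 lower at 1 to 5 FPKM. Rises outnumbered falls above that, with 1152 higher and 940 lower at 5 to 20 FPKM and 528 higher and 344 lower at 20 to 100. A few abundant genes that press down all other values stay open too. After the 50 most abundant genes of each compartment were left out (193 genes) and sums made equal, 31% of called genes rose (2129 against 4739), between the bounds of 30% and 40% set beforehand. Lower transcript diversity in BETL cells was not tested.

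Transfer cell markers were present in CZ, next to BETL. BETL cells captured with CZ would bring all markers at about the same share of their BETL level, if they held the markers in the proportions of the BETL libraries. The share ran from 0.1% for mn1 to 26.9% for betl-9, a 269-fold spread over all 14 markers (45.2-fold without mn1), which argues against such cells as the whole source. A part stays open: the shares also moved together between the CZ libraries, with 13 of the 14 markers higher in CZ replicate 3 than in replicate 1 (betl2 at 15.4% and 8.18%, MEG1 at 7.43% and 1.83%), as a varying share of BETL cells would give. The shares divide by the mean BETL level, however, and these 2 markers were also lower in replicate 1 than in replicate 3 elsewhere. In ESR betl2 was at 571 and 1220 FPKM and MEG1 at 133 and 923, and in BETL they were at 13180 and 20220, and 10310 and 15460. For them, a varying share of BETL cells cannot be told apart from a shift with the replicate number. Within single CZ libraries the spread was 190.0-fold to 646-fold. Captured BETL cells with other marker proportions were not tested and stay open. A wide spread was also not particular to CZ. Over the markers listed above 0 it was 64.9-fold in ESR, 60.6-fold in EMB, 26.1-fold in PC and 18.3-fold in CSE. In AL, shares ran from 0.0169% to 0.0902%, a 5.34-fold spread over the 13 markers listed above 0, with BETL1 listed at 0, so carry-over of BETL RNA cannot be told apart from low expression in AL: the spread lies between the 3-fold and 10-fold bounds. Among the 7 markers above 5000 FPKM in BETL, a subset tried after the values were seen and then replaced by all markers, it was 1.88-fold, which does not decide it. In the single PED and PC libraries, mn1 was at 4.73% and 2.06% of its BETL level.

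Among the 6 filial compartments, heat shock genes were highest in CZ, with list medians of 1.81, 2.14 and 1.68 in its 3 libraries (log2, relative to the mean of compartments), 1.12, 0.89 and 0.48 in CSE and -1.38, -1.29 and -1.49 in BETL. Of the single maternal libraries, PC held the list at percentile 99.97 of random lists, PED at 88.4, NU at 0.98 and PE at 0.47; hsp18f was at 199 FPKM in PC, 117 in PED and 69.8 ± 34.9 in CZ. Handling stress would also raise jasmonate and wound genes. Their median log2 change in CZ was -0.45, with a camera adjusted p = 0.126 (0.451 with an estimated correlation). This decides nothing, as the list did not pass the test in either direction. Handling and a program of the CZ cells therefore cannot be told apart here.

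The libraries were also split at random into groups of the same sizes. In 100 splits, 1 (the real split) gave as many calls in each comparison of 1 compartment with the other 5. Other splits mix compartments, so compartment differences enter the spread, and their median count was 0 or 1. The real split keeps each compartment whole and was favoured beforehand, so these splits cannot exclude chance for a single comparison. Real and highest other counts were AL 4738 against 3885, BETL 7607 against 939, CSE 3519 against 21, CZ 3438 against 48, EMB 8773 against 673, ESR 4313 against 89. For AL, CZ and ESR, the highest other split held all 3 libraries of another compartment together, so it was not a grouping free of compartment structure. For gene lists the values were 67 against 41, under the same limit. The other splits gave a median of 25 calls with the preset correlation. A single list call that was lost with an estimated correlation therefore rests on the preset value. For the 3 pairs of compartments, the 10 splits are too few to give a share under 0.05; real and highest other counts were AL vs CSE 3844 against 6, BETL vs CZ 5924 against 5 and BETL vs AL 9507 against 5.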
